A study of Mus musculus with 6 samples.

How the data were processed

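RNA from inguinal white adipose tissue of C57BL/6 mice kept at 4 °C or 22 °C for 7 days was sequenced in 6 libraries, 3 per group. Per the labels' protocols, tissue was frozen on dry ice, RNA was extracted with Trizol, and libraries were made with an Illumina TruSeq RNA kit. The labels name the source both as adipocytes and as inguinal fat tissue; values are taken here as those of whole tissue, which holds other cell types. Genome build mm10 is named in the submitters' processing notes. The aligner, the counting program, the gene annotation, the differential test and its thresholds are not given in the sources used here, nor is whether counting used strand.

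The authors deposited 1 table of 1025 genes. Its columns per library hold FPKM values, per the file headers, although the headers also carry the word count; the values are not whole numbers and are reads or fragments scaled to gene length and to the library total. The table also holds the authors' mean FPKM per group, the authors' log2 fold changes and the authors' p-values and adjusted p-values, per the file headers. The smallest absolute log2 fold change in the authors' deposited table was 1.0003 and the largest adjusted p was 0.0499, so it lists only called genes, 569 higher and 456 lower in Cold. The ratio of the smallest adjusted p to its p was that of 13002 genes tested by the authors. The authors' deposited table gave log2 fold changes within 0.05 of the log2 ratio of mean FPKM for 902 genes, with a median difference of -5e-05. Groups and replicate numbers were taken from the sample titles.

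Multiplied by merged exon length from GENCODE release M21, which uses the same assembly as mm10, FPKM values of 939 genes (91.6%) were whole multiples of 1 read in all 6 libraries, within a tolerance of 0.05; chance gives 10% per value. This gave the implied totals of 15387284 to 20260106 reads per library. The recovery of totals was tested on simulated libraries with some wrong exon lengths, and 6 of 6 totals were recovered within 0.1%. At this depth, 233 genes had a mean FPKM under 1, and 792 had a mean of 1 or more. Gene IDs were matched to symbols and GENCODE M21 positions for all 1025 genes; 1011 were protein coding.

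FPKM values are not counts, so the test fitted was limma 3.58.1 in R 4.3.3 with a trend on log2(FPKM + 1), with group as the only term, Benjamini-Hochberg adjustment over the 1025 genes and a threshold of 0.05. The prior degrees of freedom were 3.24 and the residual 4. These were estimated from called genes only, since no others are listed. The test was tested on simulated data with the levels of the 1025 genes and a fixed dispersion that was not estimated from these libraries. For Cold against Normal it recovered 95.8% of 72 genes changed 2-fold and 100% of 76 changed 4-fold at a mean FPKM of 1 or more, and 75% of 28 and 100% of 24 below that level; 3 of 825 unchanged genes (0.36%) were called. Most simulated genes were unchanged, whereas 1004 of the 1025 listed genes had an unadjusted p under 0.05, so adjustment changes little in the table and these shares are not the error rates of the 1003 calls. The camera test of gene lists, planned for tables that hold all measured genes, was not run, because unchanged genes are not in the table. In its place, as set out before the data were examined, 42 fixed lists of 906 genes were tested for direction with Fisher's exact test: higher against lower calls of a list's members against the other called genes, two-sided, with Benjamini-Hochberg adjustment over the 13 lists with at least 5 called members. As 55% of called genes were higher, 5 members that all rise give p = 0.068 in Fisher's exact test and cannot pass, whereas 5 that all fall give p = 0.018. Of the 906 genes, 216 were in the table, and 9 lists had no member there. In every list the number of called members adjusted over the list alone equalled that over all 1025 genes. Older symbols were matched through the reference tables.

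Genes named in the Results were chosen by a rule fixed before the data were examined. Exceptions are those that the last paragraph of the Results gives as named after their values had been seen. Genes named only in the additional observations were also named after their values had been seen. The rule took the 10 largest and 10 lowest log2 fold changes among called genes with a symbol other than a Gm or Rik model, a mean FPKM of at least 1 and no overlap between groups, and the 5 smallest adjusted p in each direction. It also took up to 4 members per list with at least 3 called members, all called thermogenic genes, and Ucp1, Cidea, Dio2, Ppargc1a, Elovl3, Cox8b, Prdm16, Lep, Adipoq and Fgf21. Alternatives were a pseudocount of 0.1 or 0.01, a minimum mean FPKM of 1 before or after the fit, an adjusted p of 0.01, an absolute log2 fold change of at least 1, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were voom on the recovered whole reads, adjustment over all genes tested by the authors, libraries numbered 2 and 3 only, and lists restricted to genes up to the median exon length. In the adjustment over all genes tested, unlisted genes have no limma p and were counted as larger than every listed p. The adjusted p of that setting are therefore upper bounds. The list tests without Cold 1 and without Cold 2 were added as well. The count tests planned for count tables were not run, since the values are FPKM; voom was run only as an added alternative, on the 939 genes with recovered reads. Normal libraries were 22 °C controls, and all group values are given beside them. Lists of liver and striated muscle genes, used in the closing observations, were written after the data were seen. Analyses used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.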

Results

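The study compared inguinal white adipose tissue, a subcutaneous fat depot, of C57BL/6 mice kept at 4 °C for 7 days with the same depot of mice kept at 22 °C for 7 days. The question named by the series title is how the transcriptome of white fat changes when cold exposure induces browning, the appearance of heat-producing adipocytes in a white depot. RNA sequencing of total RNA gave 6 libraries, 3 from cold-exposed mice (Cold 1 to 3) and 3 from mice at 22 °C (Normal 1 to 3). The labels do not say whether the 3 samples of a group came from separate animals, so p-values measure only the spread between these samples. The deposited table listed 1025 genes with FPKM values per library. All of them had an absolute log2 fold change of at least 1.0003 and an adjusted p of at most 0.0499 in the authors' deposited table, so genes that did not change were not listed. Library totals implied by the FPKM values were 15387284, 17019792 and 16354601 reads in Cold 1 to 3 and 19047651, 20260106 and 19742407 reads in Normal 1 to 3. The listed genes took 26.7%, 22.4% and 23.9% of these reads in Cold 1 to 3 and 16.2%, 14.6% and 14.5% in Normal 1 to 3.

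Listed members of the gene lists of heat production and of mitochondrial fuel use rose in the cold. Listed members of the white adipocyte, extracellular matrix, fibroblast and interferon lists fell, as did 9 of 10 listed macrophage markers. In each of these falling lists more members were unlisted than listed, and the direction of the unlisted ones is not known. The direction of unlisted members of the rising lists is not known either. Ucp1, the uncoupling protein of brown and beige fat mitochondria, stood at 4445 ± 898 FPKM in Cold and 526 ± 212 FPKM in Normal (SD, n = 3), 8.44-fold higher. Pdk4, a kinase that inhibits pyruvate dehydrogenase, was 13.7-fold higher, at 382.8 ± 115 FPKM against 28.0 ± 3.19 FPKM (SD, n = 3). Lep, which encodes the adipokine leptin, was 5.22-fold lower, at 32.2 ± 3.87 FPKM in Cold against 168 ± 47.6 FPKM in Normal (SD, n = 3). In limma on log2(FPKM + 1) with Benjamini-Hochberg adjustment, 1003 of the 1025 listed genes passed an adjusted p of 0.05, 552 higher and 451 lower in Cold. In 1003 genes the 3 Cold values and the 3 Normal values did not overlap, which chance gives for 10% of genes. The genes had been selected by the authors on these same libraries, so this count is not independent evidence of change. Requiring also an absolute log2 fold change of at least 1 on this scale left 520 genes, 348 higher and 172 lower.

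Thermogenic and beige adipocyte genes rose together: 24 of the 38 genes of the list were in the table, and all 24 rose. Elovl3, a fatty acid elongase, was 11.9-fold higher at 324 ± 61.9 FPKM against 27.2 ± 11.5 FPKM (SD, n = 3). Fabp3, a fatty acid binding protein of oxidative tissues, was 9.05-fold higher, and Dio2, which activates thyroid hormone, was 8.91-fold higher. Cidea, a lipid droplet protein of brown adipocytes, was 3.77-fold higher, and Cox8b, a subunit of cytochrome c oxidase, was 3.10-fold higher. The coactivators Ppargc1a and Ppargc1b were 3.50-fold and 3.94-fold higher, and the hormone gene Fgf21 was 7.29-fold higher. In the fit, limma gave Ucp1 a log2 fold change of 3.13 with a standard error of 0.305 and an adjusted p of 0.00025, and Ppargc1a 1.29 with a standard error of 0.201 and an adjusted p of 0.00093. Prdm16, a transcription regulator of brown and beige fat, was not listed, and its level is not known here. Compared with the other called genes, of which 53.9% were higher, the direction of the list gave an adjusted p of 3.8e-06 in Fisher's exact test (two-sided, Benjamini-Hochberg over 13 lists). The smaller list of UCP1-independent heat production had 4 listed members, Gpd2, Gpd1, Ckb and Alpl, which all rose; it was too small to test. Ckb and Alpl lost their calls when limma's p was adjusted over the 13002 genes tested by the authors (adjusted p 0.066 and 0.053), a setting added after the data were seen. Cited1 and Esrrg of the thermogenic list lost theirs there as well (limma adjusted p 0.1 and 0.16). Unlisted genes have no limma p and were counted as larger than every listed p, so adjusted p in this setting are upper bounds, here and below. Of the secreted factors of thermogenic fat, 5 of 20 were listed and all 5 rose (Fgf21, Bmp8b, S100b, Ptgds and Ephx2). A list of 5 called genes that all rise gives p = 0.068 in Fisher's exact test before adjustment, the lowest this test allows for a rise, so its adjusted p of 0.074 decides nothing. Ucp1 (ENSMUSG00000031710) lies on chromosome 8 from 83290352 to 83298452 in mm10, and Pdk4 on chromosome 6 from 5483351 to 5496309; both are protein-coding genes, and values refer to their exons.

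**Figure D1:**
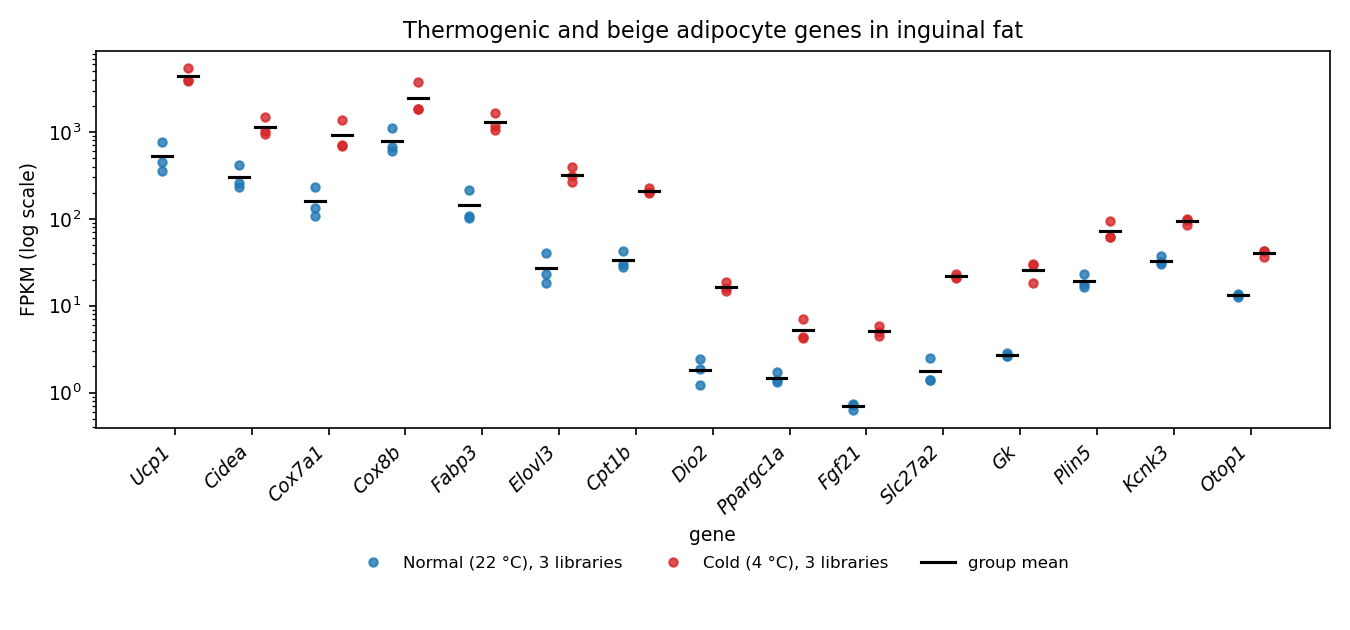
FPKM on a log axis of 15 thermogenic and beige adipocyte genes, with one point per library (blue Normal, red Cold, 3 each) and a black bar at each group mean. In each gene shown, the 3 Cold libraries lie above the 3 Normal libraries; Ucp1 rises from a mean of 526 to 4445 FPKM.

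Listed members of the lists of mitochondrial energy metabolism rose as well. Of 77 nuclear-encoded genes of oxidative phosphorylation, 47 were listed and all 47 rose, by a median log2 fold change of 1.13 (range 0.99 to 1.62), with an adjusted p of 3.7e-12 in Fisher's exact test of direction. Listing required an authors' absolute log2 fold change of about 1, which bounds this range from below. The median leaves out the 30 unlisted genes and is not that of the whole list. Cycs, which encodes cytochrome c, stood at 448 ± 52.9 FPKM in Cold and 148 ± 30.2 FPKM in Normal (SD, n = 3). Ndufa12, a subunit of complex I, was 3.15-fold higher, and Uqcrc1 and Uqcrfs1, subunits of complex III, were 2.72-fold and 2.71-fold higher. In library Cold 1 the 47 genes stood above Cold 2 and Cold 3 by a median log2 ratio of 0.67, and in Normal 1 they stood above Normal 2 and Normal 3 by 0.35. Without Cold 1 their median log2 fold change was 0.89 (range 0.73 to 1.51), and limma called 47 of 47 higher; the direction test says little here, since the genes had been selected for a fold change with Cold 1 included. All 19 listed genes of the 24 in the tricarboxylic acid cycle and pyruvate entry rose (adjusted p = 6.7e-05, Fisher's exact test), with Aco2 3.08-fold and Suclg1 3.22-fold higher. The 19 include Pdk4, an inhibitor of pyruvate dehydrogenase, so not every member is an enzyme of the cycle or of pyruvate entry. All 18 listed genes of the 34 in fatty acid oxidation rose (adjusted p = 9.8e-05, Fisher's exact test), among them Ehhadh at 107 ± 28.4 FPKM against 19.7 ± 1.96 FPKM (SD, n = 3) and Slc25a20, the carnitine carrier of mitochondria, 3.89-fold higher. Of 28 genes of glucose uptake and glycolysis, 12 were listed; 11 rose and Slc2a3, a glucose transporter, fell (adjusted p = 0.022, Fisher's exact test). Ldhb was 3.50-fold, Gapdh 3.36-fold and Pgk1 2.98-fold higher. Pfkm, the muscle form of phosphofructokinase, had 113 FPKM in Cold 2 against 20.8 and 19.6 FPKM in Cold 1 and Cold 3; it was 4.29-fold higher with all libraries and 1.69-fold higher without Cold 2. Its call (limma adjusted p = 0.043) was lost when Normal 1, Normal 2 or Normal 3 was left out (adjusted p 0.087, 0.1 and 0.071), with libraries numbered 2 and 3 only (0.081) and with adjustment over the 13002 genes tested by the authors (0.54). Among genes no longer than the median exon length of 3594 bases, a setting added after the data were seen, the fatty acid oxidation, tricarboxylic acid cycle and glycolysis lists no longer passed (adjusted p 0.063, 0.11 and 0.11). Their 9, 6 and 6 called members there all rose, and 6 that all rise give p = 0.1 in Fisher's exact test before adjustment, so the tricarboxylic acid cycle and glycolysis lists could not have passed. The shuttle list had 4 listed members of 9, all higher, with Got1 6.09-fold; the list of mitochondrial biogenesis and dynamics had 4 of 24, all higher, with Letmd1 3.97-fold. Of 15 mitochondrially encoded genes, 1 was listed, mt-Nd1, and the levels of the other 14 are not known here. It took 3.06%, 4.27% and 4.49% of reads in Cold 1 to 3 and 2.15%, 1.77% and 1.75% in Normal 1 to 3.

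**Figure D2:**
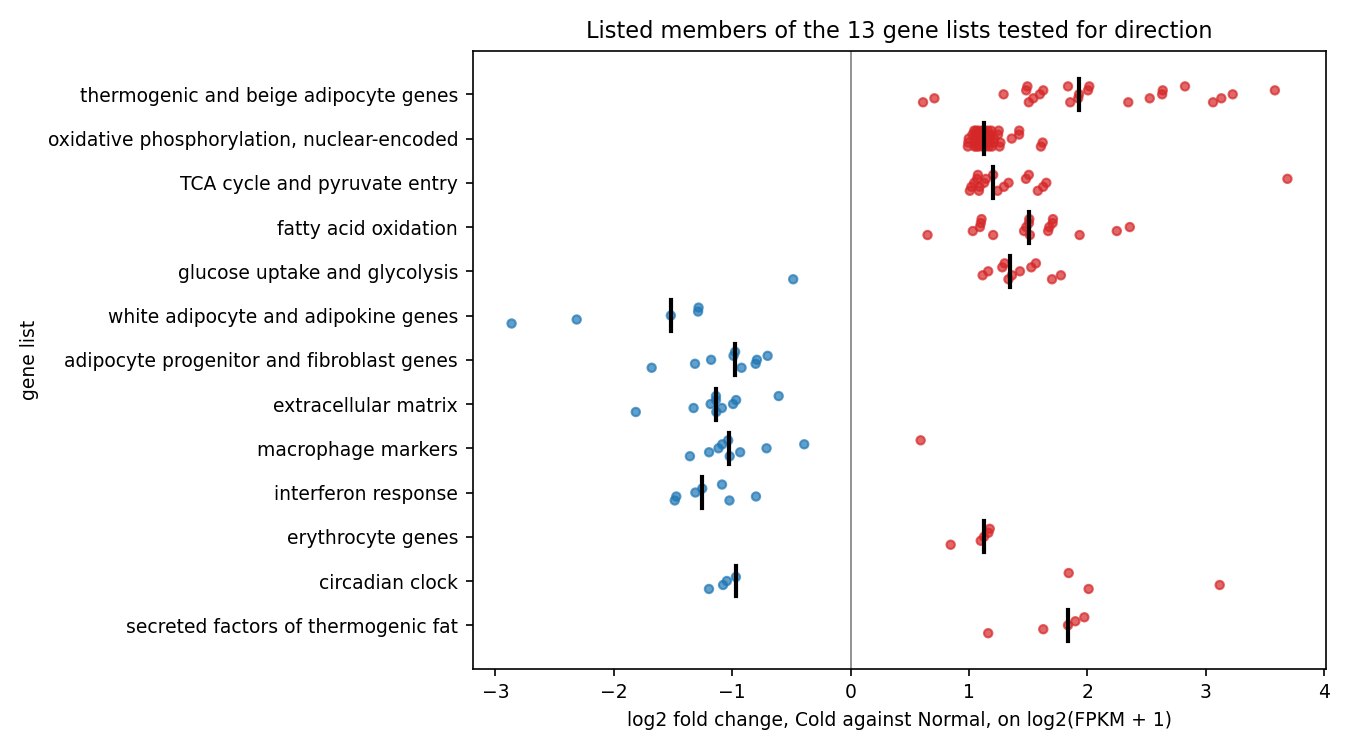
Log2 fold changes of the listed members of the 13 gene lists with at least 5 called members, on the log2(FPKM + 1) scale; each point is a gene (red higher in Cold, blue lower) and each black bar the list median. Thermogenic and mitochondrial lists lie above 0, matrix, fibroblast and interferon lists lie below 0, and circadian genes lie on both sides.

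Listed members of the white adipocyte, fibroblast and matrix lists fell. FPKM is scaled to library totals, so a larger read share of rising genes in Cold lowers the values of other genes. How much it did so was not estimated. In whole tissue, a smaller share of a cell type would also lower its transcripts. Neither was told apart from lower expression within cells, here and for the macrophage and interferon lists. All 5 listed genes of the 19 in the white adipocyte list fell (adjusted p = 0.024, Fisher's exact test): Nnat, Lep, Agt, Sncg and Dpt. Nnat, which encodes the proteolipid neuronatin, dropped from 452 ± 163 to 58.7 ± 4.94 FPKM (SD, n = 3), a log2 fold change of -2.86 with a standard error of 0.263 and a limma adjusted p of 0.00023. Lep (chromosome 6, 29060220 to 29073877) gave -2.31 with a standard error of 0.229. Adipoq, the adiponectin gene, was not listed. Sncg and Pi16 lost their calls when limma's p was adjusted over the 13002 genes tested by the authors (adjusted p 0.097 and 0.068). All 9 listed genes of the 20 in the progenitor and fibroblast list fell (adjusted p = 0.0016, Fisher's exact test), with Pi16, a marker of fibroblast-like progenitors, 3.22-fold lower (4.99-fold without Cold 1) and the proteoglycan genes Dcn and Lum 2.52-fold and 2.31-fold lower. All 10 listed genes of the 32 in the extracellular matrix list fell (adjusted p = 0.00083, Fisher's exact test). Fn1, the fibronectin gene, stood at 5.38 ± 1.72 FPKM in Cold and 21.3 ± 5.33 FPKM in Normal (SD, n = 3). The collagen genes Col3a1 and Col1a2 were 2.28-fold and 2.24-fold lower, and the protease gene Mmp2 was 2.55-fold lower. Outside the lists, Adamts5, a protease that cleaves proteoglycans, was 4.55-fold lower, and Podn, a small proteoglycan, was 4.02-fold lower. Of TGF-beta and fibrosis regulators, Inhbb, Tgfb3 and Bmp7 fell and Serpine1 rose.

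Most listed macrophage markers and all listed members of the interferon list also fell. Of 27 macrophage markers, 10 were listed; 9 fell and Arg1 rose (adjusted p = 0.011, Fisher's exact test). Mrc1, the mannose receptor gene, stood at 4.67 ± 0.50 FPKM against 11.99 ± 1.35 FPKM (SD, n = 3), 2.57-fold lower, and Retnla, Mgl2 and C1qc were 2.42-fold, 2.18-fold and 2.12-fold lower. The list no longer passed among genes up to the median exon length (adjusted p = 0.078). Arg1, an enzyme also abundant in liver, was at 0.85, 1.16 and 0.30 FPKM in Cold 1 to 3 and at 0.12, 0.066 and 0.27 FPKM in Normal 1 to 3, 5.05-fold higher, or 8.35-fold without Normal 3. All 7 listed genes of the 22 in the interferon list fell (adjusted p = 0.0067, Fisher's exact test), with Ifi27l2a at 1521 ± 721 FPKM against 3996 ± 767 FPKM (SD, n = 3) and Ifit3 at 8.97 ± 1.08 FPKM against 26.95 ± 3.67 FPKM (SD, n = 3). Adjusted over the 13002 genes tested by the authors, where adjusted p are upper bounds, limma no longer called Retnla, C1qc, Ifi27l2a and Iigp1 (adjusted p 0.056, 0.087, 0.054 and 0.11). Arg1 could not keep its call there either, since its limma adjusted p over the listed genes was 0.015 against 0.0086 for Iigp1. The complement genes C7 and C4b were 5.83-fold and 3.44-fold lower, and F13a1, a coagulation factor gene expressed in macrophages, was 3.44-fold lower. The listed T cell, B cell, inflammatory cytokine and antigen presentation genes numbered 0, as did mammary, keratinocyte and mesothelial markers, cholesterol synthesis and branched-chain amino acid catabolism genes; the table does not show whether they were measured.

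**Figure D3:**
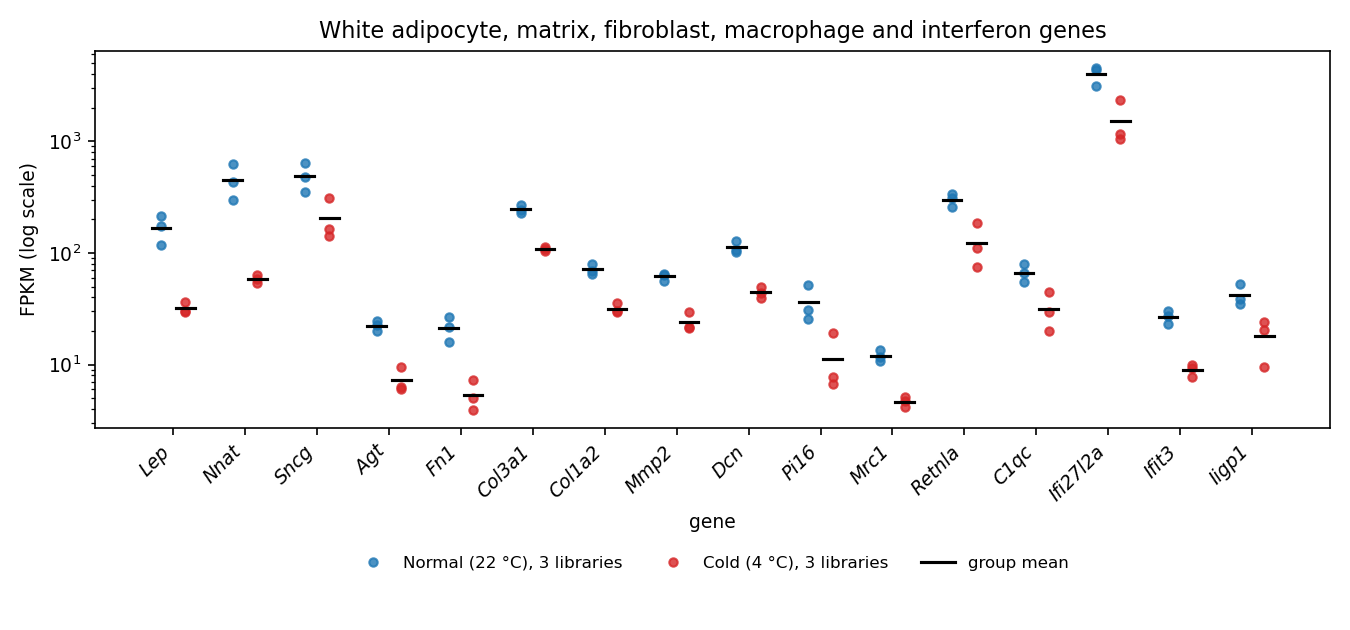
FPKM on a log axis of 16 genes of the white adipocyte, matrix, fibroblast, macrophage and interferon lists, with one point per library (blue Normal, red Cold, 3 each) and a black bar at each group mean. In each gene shown, the 3 Cold libraries lie below the 3 Normal libraries; Lep falls from a mean of 168 to 32.2 FPKM.

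Other lists held genes that moved both ways or had few listed members. Of 18 circadian clock genes, 7 were listed: Nr1d1, Nr1d2 and Dbp rose, and Nfil3, Npas2, Cry1 and Cry2 fell (adjusted p = 0.71, Fisher's exact test). The test looks for a common direction, so it cannot tell whether clock genes that moved in opposite directions changed together. Whether the groups were collected at the same time of day was not examined. Nr1d1, which encodes a repressor in the clock, was 10.6-fold higher, at 44.2 ± 10.7 FPKM against 4.18 ± 0.965 FPKM (SD, n = 3). Of 9 erythrocyte genes, 5 were listed and all 5 rose, with Hbb-bs 2.26-fold higher; as for the secreted factors, 5 members that rise could not have passed the test of direction. The globin genes of each cluster share near-identical sequence, so how reads were split among them is uncertain. The lists with 1 to 4 listed members were not tested. In these, Pck1 and Plin2 (triglyceride synthesis and lipid droplet), Cebpb and Esrra (adipogenic transcription factors), Adcy3 (lipolysis), Mb (skeletal muscle), S100b (nerve), Cenpe (cell cycle), Egln3 (hypoxia), Trib3 (stress), Nr4a1 and Fosb (immediate early), Fabp5 and Vldlr (lipid uptake) and Pdk4 (fasting) rose. Pnpla3 (lipogenesis), Ldlr (lipid uptake), Angpt1 (angiogenesis), Lyve1 (endothelial), Tpsb2 and Cma1 (mast cell), Trpv1 (smooth muscle list), Sox10 and Ncmap (Schwann cell), Socs3, Sdf2l1, Fkbp5 and Tsc22d3 fell. Fosb lost its call without Cold 2 or without Normal 2 (limma adjusted p 0.064 in each), and both Fosb and Ncmap lost theirs with libraries numbered 2 and 3 only (0.067 and 0.083) and with adjustment over the 13002 genes tested by the authors (0.28 and 0.1).

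The genes with the largest changes included some that differed widely between the Cold libraries. Mup14, of the major urinary protein family, had 640, 1.06 and 307 FPKM in Cold 1 to 3 and 0.038, 0.107 and 0.037 FPKM in Normal 1 to 3 (limma adjusted p = 0.016). Its adjusted p was 0.053 without Cold 1, 0.13 with libraries numbered 2 and 3 only, 0.17 with voom on recovered reads and 0.21 with adjustment over the 13002 genes tested by the authors. Its near-identical family members make the assignment of its reads uncertain. Mb, the myoglobin gene, had 30.7, 133 and 16.7 FPKM in Cold 1 to 3 and 1.48, 1.06 and 2.44 FPKM in Normal 1 to 3 (limma adjusted p = 0.0012), 36.2-fold higher, or 14.3-fold without Cold 2. On lists written after the data were seen, 38 of 66 liver genes were listed and all 38 rose, with Alb, the albumin gene, at 57.9 ± 12.8 FPKM against 21.3 ± 7.37 FPKM (SD, n = 3). Agt, which liver also expresses, was not on the liver list and fell, so this count depends on how the list was made. Of 62 striated muscle genes 18 were listed, and limma called 12 of them higher with all libraries and 16 without Cold 2. Of the 29 skeletal muscle markers fixed before the data were examined, 1 was listed, Mb. Gmpr, a purine nucleotide enzyme gene, was 17.4-fold higher, and Phospho1, a phosphatase gene, was 10.7-fold higher. The mitochondrial carrier genes Slc25a34 and Slc25a42 were 11.9-fold and 4.16-fold higher, and Perm1, a regulator of oxidative genes in muscle, was 13.9-fold higher at 10.2 ± 1.85 FPKM against 0.731 ± 0.102 FPKM (SD, n = 3). Sult1e1, an estrogen sulfotransferase gene, was 5.87-fold lower, Alkal2, a receptor ligand gene, 6.98-fold lower, and Il1r2, an interleukin 1 decoy receptor gene, 4.44-fold lower; without Cold 1, Sult1e1 was 9.23-fold and Il1r2 7.00-fold lower. Folds here are ratios of mean FPKM; the limma fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Genes of a list are regulated together and are not independent, whereas Fisher's exact test treats them as independent. The list p-values therefore describe these samples and may be too small, by an amount that was not estimated. Slc2a3, Ephx2, Dpt, Arg1, Alb, mt-Nd1, Npas2, Cry1 and Cry2, and Pck1, Plin2, Cebpb, Esrra, Adcy3, Cenpe, Egln3, Trib3, Pnpla3, Angpt1, Lyve1, Tpsb2, Cma1, Trpv1 and Sdf2l1 of the lists too small to test, were named after their values had been seen.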

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

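Settings marked as added were chosen after the data were seen. Across 16 alternatives, the number of genes called by limma stayed within 1.5 times the 1003 of the original fit in 15. An absolute log2 fold change of at least 1 left 520. Adjustment over the 13002 genes tested by the authors gave 742 calls (added), voom on recovered reads 920 of 939 (added), and libraries numbered 2 and 3 only 922 (added). The 742 calls are a lower bound for these p, since unlisted genes have no limma p and were counted as larger than every listed p. Leaving out one library gave 965 to 1002 calls. The 109 named listed genes gave 1723 values under the alternatives: 1682 kept direction and call, 41 lost the call, in 21 genes, and 0 changed direction. The authors had selected all listed genes on these same libraries, and some named genes were chosen for no overlap between groups. This favours kept calls and directions, here and in the counts of called genes above. Settings that change only a threshold, a filter after the fit or the adjustment keep the original fold changes, so no direction could change there. Of the 41, adjustment over the 13002 genes accounts for 14 (Mup14, Cited1, Esrrg, Ckb, Alpl, Pfkm, Sncg, Pi16, Retnla, C1qc, Ifi27l2a, Iigp1, Ncmap and Fosb) and the log2 fold change minimum for 12. Others were 4 at an adjusted p of 0.01 (Mup14, Esrrg, Pfkm and Fosb), 4 with libraries numbered 2 and 3 only (Mup14, Pfkm, Ncmap and Fosb), 6 without 1 library (Mup14, Pfkm and Fosb) and 1 with voom (Mup14). Of the 42 lists, 10 passed in the direction test, and 7 of the 8 alternatives gave 9 or 10 lists. For lists, the fits without Cold 1, without Cold 2 and with libraries numbered 2 and 3 only were added. No other single library was left out for lists. Restricting to genes up to the median exon length (added) gave 3, and ended the calls of fatty acid oxidation (adjusted p = 0.063), the tricarboxylic acid cycle (0.11), glycolysis (0.11) and macrophage markers (0.078). The 6 called members of each of the tricarboxylic acid cycle and glycolysis lists all rose there, which gives p = 0.1 in Fisher's exact test before adjustment, its lowest for a rise, so these tests could not have passed; the 9 of fatty acid oxidation all rose as well. Higher genes had shorter exons than lower genes in this table (median 3077 against 4318 bases). The progenitor, matrix, interferon, circadian and secreted-factor lists then had under 5 called members and no value, as had the progenitor and erythrocyte lists under the log2 fold change minimum. The replicate block gave 998 calls; correlations of deviations between same-numbered libraries were 0.312, 0.047 and -0.079, not every library correlated best with its own number, and nothing shows that the numbers pair the samples. The edgeR and DESeq2 alternatives were not run, because the values are FPKM, and the camera and fry alternatives were not run, because unchanged genes are not listed. For genes simulated below 1 FPKM, a range where the table holds 233 genes, the 2-fold change was recovered in 75% of 28. Depth was not varied, and the log2(FPKM + 1) scale also shrinks changes of low values, so the cause of this loss was not tested.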

Other observations

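All tests in this part were chosen or written down after the values were seen. Families of genes were formed from the letters that open the symbol and tested for direction as the lists were (16 families, Benjamini-Hochberg over them). The Cox family, mostly subunits and assembly factors of cytochrome c oxidase, had 11 called genes, all higher (adjusted p = 0.024, Fisher's exact test). The cytochrome P450 family (Cyp) had 7 called genes, all higher (adjusted p = 0.037), with Cyp2b10 at 8.51 ± 4.15 FPKM against 1.83 ± 0.724 FPKM (SD, n = 3) and Cyp1a1 at 14.7 ± 3.61 FPKM against 6.69 ± 0.896 FPKM (SD, n = 3). Of these 7, Cyp2a5, Cyp2c70 and Cyp3a11 are on the liver list used later in this part. Their means in Cold were 0.734, 0.859 and 0.512 FPKM, with Cold 3 the lowest Cold library in all 3. Cyp2c70 and Cyp3a11 were highest in Cold 2, at 1.45 and 1.06 FPKM, against 0.755 and 0.306 FPKM in Cold 1. The major urinary protein family (Mup) had 8 called genes, all higher (adjusted p = 0.037), and its near-identical members make the assignment of reads uncertain. Ndufa (8 genes) and Ndufs (7 genes) were all higher, and Atp had 11 higher and 1 lower (adjusted p = 0.037 each). The Col stem, collagens, had 1 called gene higher and 8 lower (adjusted p = 0.037). The 6 called genes with the stem Cd, surface molecules, fell (adjusted p = 0.037): Cd163, Cd248 and the lectin receptor genes Cd209a, Cd209d, Cd209f and Cd209g, with Cd209f at 7.57 ± 3.34 FPKM against 23.5 ± 5.69 FPKM (SD, n = 3). These families overlap with the fixed lists and with the liver list, and the test was not planned.

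Some genes of complement and the acute phase, picked after their values were seen and not tested as a group, had the following values. C2 stood at 12.6 ± 1.99 FPKM in Cold and 40.8 ± 7.15 FPKM in Normal (SD, n = 3; limma adjusted p = 0.0004), C3 at 150 ± 5.55 FPKM against 304 ± 46.3 FPKM (SD, n = 3; limma adjusted p = 0.00095), and the inhibitor genes Cfh and Serping1 at 1.72 ± 0.393 against 6.09 ± 0.870 FPKM and 41.6 ± 13.8 against 110 ± 15.2 FPKM (SD, n = 3). Hp, which encodes the acute-phase protein haptoglobin and is expressed in adipocytes, stood at 538 ± 233 FPKM in Cold and 1710 ± 486 FPKM in Normal (SD, n = 3; limma adjusted p = 0.0028). Lbp, the lipopolysaccharide binding protein gene, at 2.96 ± 0.647 against 8.80 ± 1.47 FPKM, and Serpina3n, a serine protease inhibitor gene, at 66.4 ± 14.7 against 174 ± 16.6 FPKM, fell as well (SD, n = 3; limma adjusted p = 0.00069 and 0.00057). Other acute-phase genes rose. Hpx, the hemopexin gene, had 5.33, 5.29 and 3.26 FPKM in Cold 1 to 3 and 0.315, 0.296 and 1.55 FPKM in Normal 1 to 3 (limma adjusted p = 0.0012), and Orm3, an orosomucoid gene, stood at 9.55 ± 2.26 FPKM against 3.44 ± 1.11 FPKM (SD, n = 3; limma adjusted p = 0.002). Fgg and Serpina1a to Serpina1e rose as well, and these and Hpx are on the liver list used later in this part.

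Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many called genes as the real one, which is the real one itself (1003 genes); the highest other gave 1. With 10 splits no share under 0.05 is possible. The genes were also selected on the real split, which favours it.

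Many transcripts typical of liver were higher in Cold. Of 66 textbook liver genes, 38 were listed, all higher, among them Alb at 65.9, 64.5 and 43.2 FPKM in Cold 1 to 3 and 15.6, 18.8 and 29.6 FPKM in Normal 1 to 3, and Fabp1 at 29.8, 10.9 and 8.18 FPKM against 0.0949, 0.268 and 3.11 FPKM. In 94.7% of the 38, Cold 3 was the lowest Cold library and Normal 3 the highest Normal library, against 6.2% of the 531 other higher genes. The list and this order were picked after the values were seen and the genes vary together, so these shares describe the pattern and do not test its source. Hp, Lbp, C3, Agt and Pon1, which liver also expresses, were not on the list and fell. That all 38 were higher therefore depends on how the list was made. The Mup genes, also typical of liver, were not on the list; 4 of the 9 listed had this order, and Mup14, Mup11, Mup16, Mup15 and Mup17 did not, so that 40 of 47 genes had it with them included. Liver RNA from one source in differing amounts and expression induced in fat at 4 °C cannot be told apart. Both would give the 38 of 38 called higher, and the levels differed between the groups on average. Level did not follow group in every library. Normal 3 reached the level of Cold 3 in Fgg (0.799 against 0.789 FPKM) and Serpina1e (3.38 against 3.29 FPKM). In Alb and Fabp1, Normal 3 stayed below Cold 3. Of the 38, 5 had a Normal mean FPKM of 1 or more and 1 is in the fixed lists (Arg1).

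The nuclear-encoded oxidative phosphorylation genes stood higher in Cold 1 than in Cold 2 and Cold 3 by a median log2 ratio of 0.67, and Normal 1 stood above Normal 2 and Normal 3 by 0.35, with Cold 1 the highest Cold library in 47 of the 47 genes and Normal 1 the highest Normal library in 46. Across the 456 genes lower in Cold, the same ratio fell with exon length (Spearman rho = -0.44; genes are not independent replicates), so a length-related difference of library Cold 1 may be part of it. It leaves a median excess of 0.25 (quartiles 0.088 and 0.352, 40 of 47 genes above 0) over 20 length-matched other genes each. This argues against merged exon length as the whole difference. Merged length covers all annotated exons of a gene, so the length of the expressed transcript was not matched. Whether that length accounts for the whole difference is therefore not decided. Why the remainder differs and why Normal 1 is higher as well was not tested; the labels do not say whether libraries numbered 1 share a day, batch or litter, and no biological explanation was tested.

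Striated muscle-type transcripts were highest in Cold 2. Of 62 muscle genes, 18 were listed, all higher in Cold, and in 88.9% of them Cold 2 was the highest Cold library, against 18.3% of 551 other higher genes, on a list written after the values of Cold 2 were seen. Of the 29 skeletal muscle markers fixed before the data were examined, 1 was listed, Mb. Actn2 had 10.1 FPKM in Cold 2 and 0.925 and 0.564 FPKM in Cold 1 and Cold 3. Whether muscle RNA in Cold 2 accounts for this stays open, since these genes vary together in 1 library, and abundant contractile genes such as Acta1 and Ckm are not listed. Without Cold 2, 16 of the 18 were called higher, with a median log2 fold change of 0.71, which argues against Cold 2 alone as the source of the rise of the listed genes, although genes raised in Cold 2 alone are less likely to be listed; 12 of them had a Normal mean FPKM of 1 or more and 2 are in the fixed lists (Mb and Pfkm).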
